A study of Mus musculus with 5 samples.

How the data were processed

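RNA of 5 cultures of mouse fetal liver pro-B cells was measured on 1-colour (Cy3) Agilent arrays. The cultures were started from livers of embryos at 16.5 days post coitum and grown on stromal cells with interleukin-7, per the labels' protocols. All were treated with 4-hydroxytamoxifen for 24 hours, which activates a Cre recombinase fused to the oestrogen receptor, and were cultured for 4 more days before RNA was taken. Labelled cRNA was made from 0.2 µg of total RNA with an oligo-dT primer, per the labels. The groups were taken from the genotype in the sample titles. There were 2 heterozygous control arrays (numbers 3 and 6 in their titles), with 1 Ebf1 allele floxed, so that Cre can delete it. The other 3 arrays had both alleles floxed (numbers 4, 5 and 7). They are called deleted here, although the titles give the floxed genotype and not the deletion. The titles also carry a first number that is 111 in both controls and 93 in all 3 deleted samples, so whatever that number stands for and the genotype cannot be told apart.

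The authors deposited 1 intensity per array feature, on a linear scale, made with Agilent Feature Extraction per the submitters' processing notes (version not given in the sources used here). The deposited intensities are all above zero, with array minimums between 1.87 and 2.56. Their 75th percentiles range from 306 in deleted 5 to 430 in deleted 7. How background was handled, and any spot flags, are not given in the sources used here. The table had 45018 features, of which 33653 had 1 gene symbol in the platform annotation, 56 had several and were not named, and 11309 had none there; which of these are control spots is not given in the sources used here, so all features entered the percentile used for scaling. Of the named features, 33517 matched a mouse reference gene table by gene ID, and no symbol changed. The number of arrays limits the precision. No genome was used, so probe positions are not given.

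For the results here, log2 intensities were taken and each array's 75th percentile was subtracted. All levels below are therefore log2 intensities relative to the 75th percentile of the array. Each gene was represented by its probe with the highest mean over the 5 arrays. The annotation does not tell repeated spots of one probe from different probes, so repeats were not averaged in the main setting, and genes with repeated spots take the brightest one. A gene was tested if at least 2 of the 5 arrays exceeded the array's 40th percentile, which kept 13419 of 19087 genes. Where every array of a group lay at or below its 40th percentile, that percentile was used as the lower limit and the change is given as "at least N-fold". This limit stands in for detection flags.

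The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment over the 13419 genes and a threshold of 0.05. Every adjusted p below is from that fit unless another is named. Fold changes are deleted over control with standard errors (SE) from the fit, and group levels are means ± SD. Sets of genes were tested with limma's camera (inter-gene correlation 0.01) and Benjamini-Hochberg adjustment over 16 lists. The lists, fixed before the data were examined, were B-lineage receptor and signalling, B-lineage transcription factors, V(D)J recombination, B-cell surface and adhesion proteins, MHC class II presentation, NK and innate lymphoid cells, T cells, myeloid cells, stem and progenitor cells, erythroid cells, stromal cells, cell cycle, p53 pathway and apoptosis, the IL-7 receptor and STAT5 pathway, interferon-stimulated genes, and glycolysis and hypoxia. A list of 4 sex-linked genes served as a check of the samples. List members without a named probe were not analysed here. Macrophage, dendritic cell and later B-cell stage lists were added after the data were seen.

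The genes named in the text follow a rule fixed beforehand: Ebf1; the 8 largest increases and 8 largest decreases among genes past the threshold whose groups did not overlap; and up to 3 members of each list past the threshold with the largest change, or the member with the largest change where none passed. A gene outside this rule is named as an example after its values were seen. The labels do not say that the samples of a group came from separate embryos. The p-values therefore weigh the group difference against the spread between these samples, moderated by the spread over all genes. The groups share no sample numbers. The fit and camera were tested on 10 simulated data sets of 13419 genes with the means of this comparison. Variances were drawn from the prior of its fit, and 200 genes were changed in each set. The fit recovered a mean of 83.9% of 8-fold changes and 16.8% of 2-fold changes, and 4.74% of calls were false. In the data 2324 genes passed, and the adjusted threshold is less strict when more genes change, so these shares need not hold there. The runs do not test the variance model, which they take as given. The shifted list was called in 10 of 10 runs with 0 unshifted lists called. Simulated genes varied independently, so these runs do not test camera for lists whose genes vary together. Alternatives covered the scaling, the filter, a floor, the use of probes, the variance model, thresholds, the set test, each array left out and, added after the data were seen, scaling over named probes alone, the arrays high in Xist as a block, and the arrays low in Xist alone. Figures were drawn with matplotlib 3.10.9.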

Results

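Ebf1 (early B-cell factor 1) is a transcription factor of the B lineage. Its loss was studied in cultured fetal liver pro-B cells, which are early B-cell precursors. The comparison asked how expression differed 4 days after tamoxifen between 2 groups. These were cells with both Ebf1 alleles floxed, called deleted (n = 3), and treated cells with 1 allele not floxed (n = 2). The sum of intensities per array ranged from 66780400 in deleted 5 to 79527100 in deleted 7. Over the tested genes, the arrays of a group correlated with Pearson's r of 0.979 (control) and 0.979 to 0.982 (deleted), against 0.926 to 0.959 between groups. No pair of arrays shared an identical value.

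Ebf1 itself was represented by 3 probes, which had different fold changes. The probe for AK036716 fell 8.11-fold in deleted cells, from -1.39 ± 0.12 (SD, n = 2) to -4.41 ± 0.53 (SD, n = 3), with a log2 fold change of -3.02 (SE 0.35, limma adjusted p = 0.0037 over 28007 probes). The brightest probe, for NM_007897, stood at 2.48 ± 0.03 in control and 2.23 ± 0.13 in deleted cells, a log2 fold change of -0.25 (SE 0.15, 95% interval -0.60 to 0.11, adjusted p = 0.32). The dim probe for AK042875 had a log2 fold change of 0.44 (SE 0.24, adjusted p = 0.27). Where these probes lie relative to the deleted part of the gene was not determined here, and a probe outside that part would not test the deletion. The submitters' design notes state that Ebf1 expression was no longer detectable in the treated floxed cells.

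**Figure D1:**
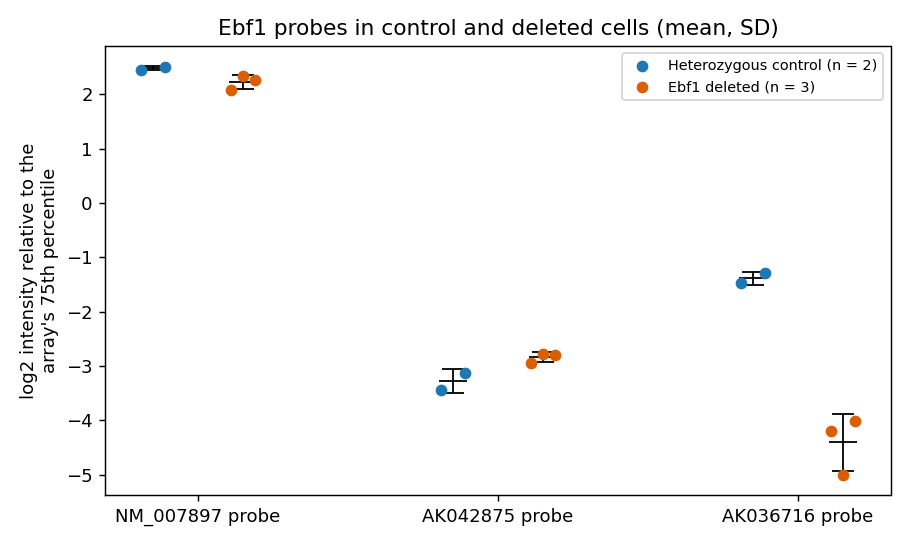
Log2 intensity relative to the array's 75th percentile (vertical axis) for the 3 Ebf1 probes (horizontal axis), with points for arrays and black marks for the mean and SD of 2 control and 3 deleted samples. The AK036716 probe is lower in all 3 deleted samples (means -1.39 and -4.41), whereas the NM_007897 probe has means of 2.48 and 2.23.

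Deleted cells differed broadly from controls. Of 13419 genes, 1151 were higher and 1173 lower in deleted cells at an adjusted p under 0.05, and 644 and 891 of these changed at least 2-fold. Of the 8 largest increases 4 were in MHC class II chains, which present antigen to T cells. H2-Aa rose 187-fold (log2 fold change 7.55, SE 0.27), H2-Eb1 123-fold (6.94, SE 0.26) and H2-Ab1 90.8-fold (6.51, SE 0.36). H2-Ea was in the lowest 40 percent of features in both controls and was at least 54.1-fold higher. Jhy, a gene linked to cilia, and Wfdc18 were likewise low in both controls and were at least 336-fold and 58.7-fold higher. A second probe gave log2 fold changes of 4.75 for Jhy, 6.47 for H2-Aa and 7.39 for Wfdc18, and other H2-Ab1 probes gave 5.51 to 6.54. Wfdc17, of the same whey acidic protein family as Wfdc18, rose by 7.58 (SE 0.33) on the log2 scale, and Ly86, whose product pairs with the receptor Cd180, by 7.07 (SE 0.44). Ly86 exceeded the 40th percentile in 1 of 2 controls. Without control 3 and without control 6 the log2 fold change was 6.49 and 7.66 for Ly86, and 7.11 and 5.90 for H2-Ab1.

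At the brightest probes the largest decrease was in Chd3, a chromatin remodeller, which fell by 7.66 (SE 0.35) on the log2 scale. Chd3 went from 3.31 ± 0.08 (SD, n = 2) to -4.35 ± 0.59 (SD, n = 3). Its 3 further probes gave log2 fold changes between -7.03 and -4.04. The mean of the Chd3 probes gave -5.755, so its rank depends on the probes used. Scin, an actin-severing protein, fell by 6.30 (SE 0.53) and Gng4, a G protein subunit, by 6.03 (SE 0.51). Rpl3l, Ttll11, Rcan2 and Rab6b had log2 fold changes of -7.47, -7.18, -6.71 and -6.16, and each exceeded the 40th percentile in only 1 of 3 deleted arrays. A second probe gave -4.12 for Rcan2 and -4.73 for Rab6b. Slc9a2, a sodium-proton exchanger, did so in none and was at least 37.8-fold lower, a limit that was 11.8-fold without control 3 and 121-fold without control 6, and the mean of its probes had a log2 fold change of -3.97. Without control 3 and without control 6 the log2 fold change was -5.91 and -8.45 for Ttll11 and -5.50 and -7.10 for Scin. It was -6.80 for Rpl3l, -7.94 for Rcan2 and -6.93 for Rab6b without deleted 4, -5.90 for Rcan2 without deleted 5 and -5.78 with array weights, and -8.20 for Rpl3l without deleted 7. The limma adjusted p of these 16 genes lay between 3.52e-05 and 0.0120, and Rcan2 did not pass without control 3 (adjusted p = 0.0568) or without control 6 (0.0569). The number of changed genes fell from 2324 to 703 without control 3, to 1449 without control 6, to 1416 without deleted 4 and to 1274 without deleted 5. Of the changed genes 49.5% were higher, against 38.6% without scaling between arrays and 56.4% with scaling by the median. Genotype coincided with the first number of the sample titles and cannot be told apart from what it stands for.

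**Figure D2:**
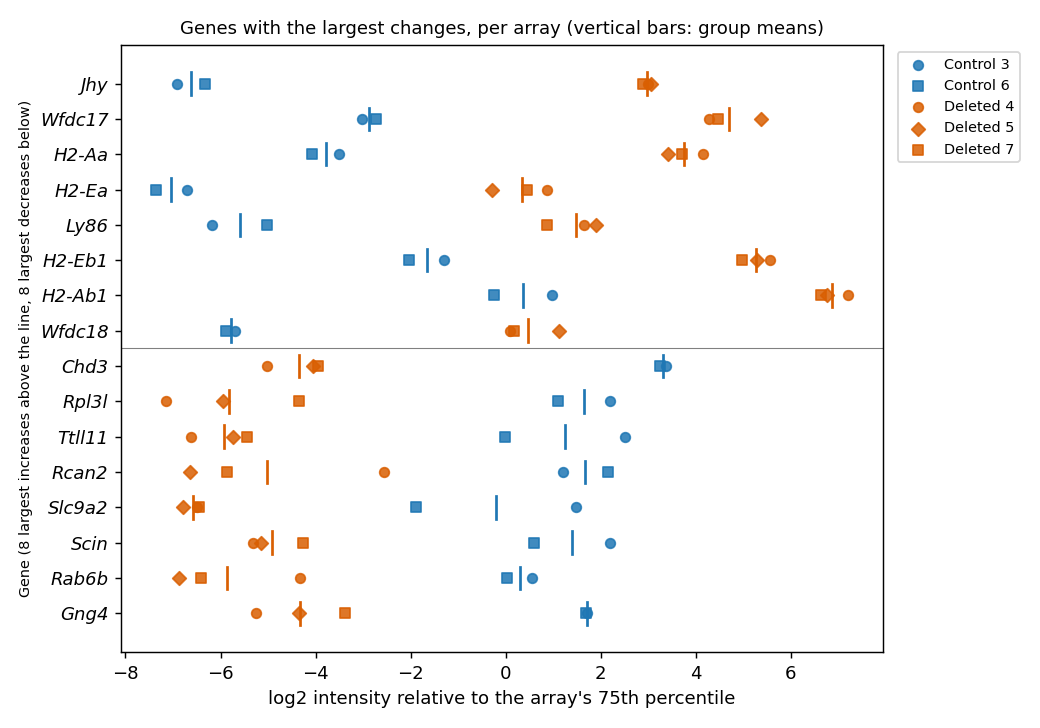
Log2 intensity relative to the array's 75th percentile (horizontal axis) of the 16 genes with the largest changes (vertical axis), with 1 point per array and vertical bars for group means. The genes were chosen so that the 3 deleted arrays lie apart from both control arrays. H2-Ab1 has means of 0.36 in control and 6.87 in deleted cells.

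The MHC class II list rose as a group. Of its 10 tested members 8 were higher and 0 lower (8 higher and 1 lower when adjusted over the list alone), with a mean log2 fold change of 3.99. Besides the 3 chains above, Ciita, the transactivator of these genes, rose 60.2-fold (adjusted p = 0.0011), and Cd74, the invariant chain, rose 24.3-fold from 2.27 ± 0.35 to 6.87 ± 0.23 (adjusted p = 0.00022). H2-DMa, H2-DMb1 and H2-DMb2, chains of the peptide-loading factor, rose 14.1-, 6.83- and 5.95-fold. H2-Oa and H2-Ob, subunits of the regulator of that factor, had log2 fold changes of -0.48 and -0.24 without passing the threshold, and a second H2-Ob probe gave 1.21. Camera called the list (adjusted p = 5.2e-07; adjusted p = 0.30 with an estimated correlation). In the same arrays the myeloid list had a mean log2 fold change of -0.07 (camera adjusted p = 0.58) over members that went both ways, with Cebpb at 3.34, Tyrobp at 1.56 and Itgam at -2.09. Outside that list, Wfdc17 and Ly86 had log2 fold changes of 7.58 and 7.07. Probes of closely related class II chains can share signal.

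Igll1 and Vpreb2, genes of the surrogate light chain of the pre-B-cell receptor, were lower, as was Vpreb3. Igll1, which encodes the lambda 5 component of that chain, fell by 4.39 (SE 1.02, adjusted p = 0.032) on the log2 scale. Vpreb2 and Vpreb3 had log2 fold changes of -3.66 (SE 0.77, adjusted p = 0.024) and -3.13 (SE 0.56, adjusted p = 0.015). Vpreb1 and Vpreb2 are near-identical and their probes may not separate them. Of 18 tested members of the receptor and signalling list 7 were lower and 3 higher (10 and 4 adjusted over the list alone), the higher ones being Bank1, Cd22 and Ptpn6. Cd79a and Cd79b, the signalling chains, had log2 fold changes of 0.01 (95% interval -0.93 to 0.96) and -0.04 (95% interval -0.60 to 0.51). The list was lower by camera (mean log2 fold change -0.92, adjusted p = 0.026; adjusted p = 0.33 with an estimated correlation), and its call was lost without control 6 (adjusted p = 0.15). Igll1 and Vpreb2 did not pass without control 3 (adjusted p = 0.169 and 0.140), control 6 (0.0818 and 0.0616) or deleted 5 (0.0864 and 0.0798), nor Vpreb3 without control 3 (0.0881) or control 6 (0.0546). With all arrays Igll1 and Vpreb2 also did not pass without the variance trend (0.0694 and 0.0559) or with robust variances (0.0740 and 0.0584). Without deleted 4 the log2 fold changes of Igll1, Vpreb2 and Vpreb3 were -3.29, -2.89 and -2.51, and without deleted 7 those of Igll1 and Vpreb2 were -5.22 and -4.35, while array weights gave -5.08 for Igll1.

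Among 17 B-lineage transcription factors, 4 were lower and 2 higher (5 and 2 adjusted over the list alone). Tcf3, which encodes the E2A proteins, fell by 1.61 (SE 0.21, adjusted p = 0.0052), and Myb fell by 1.55 (SE 0.24, adjusted p = 0.0093). Pou2af1 and Lef1 were also lower, whereas Mef2c rose by 1.63 (SE 0.28, adjusted p = 0.013), as did Bcl11a. Pax5, a factor that maintains B-cell identity, had a log2 fold change of -0.53 (95% interval -1.13 to 0.06, adjusted p = 0.19). The list shift was small (mean log2 fold change -0.32, camera adjusted p = 0.041; adjusted p = 0.38 with an estimated correlation), and it was lost without control 6 (adjusted p = 0.15), without deleted 4 (adjusted p = 0.0583) and with the arrays high in Xist as a block (adjusted p = 0.0581, with the mean again -0.32). Myb did not pass without control 3 (adjusted p = 0.0644), nor Mef2c without control 6 (0.0599) or, with all arrays, as the mean of its probes (log2 fold change 0.93, adjusted p = 0.0760).

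Of 18 tested surface and adhesion genes of B cells, 6 were lower and 3 higher (8 and 3 adjusted over the list alone). Il2ra, the interleukin-2 receptor alpha chain, fell by 3.25 (SE 0.53, adjusted p = 0.010), and Bst1 and Cd24a, an early B-cell surface marker, had log2 fold changes of -3.06 (SE 0.79, adjusted p = 0.043) and -2.73 (SE 0.32, adjusted p = 0.0038). Other Il2ra probes gave -4.07 to -3.14. Cd2, Cd55 and Ptprc were the higher members. The mean log2 fold change was -0.79 (camera adjusted p = 0.026; adjusted p = 0.52 with an estimated correlation), and the call was lost without control 6 (adjusted p = 0.15). Bst1 did not pass without control 3 (adjusted p = 0.197), control 6 (0.114) or deleted 5 (0.116), nor, with all arrays, without the filter (0.0640), in a fit on probe means that left its own value unchanged (0.0518), without the variance trend (0.0861) or with robust variances (0.0934). Its log2 fold change was -2.26 without deleted 4 and -3.80 without deleted 7.

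V(D)J recombination genes, which assemble antigen receptor genes, were lower as a list. Of 10 tested members 5 were lower and 0 higher (6 and 2 adjusted over the list alone). The DNA ligase gene Lig4 fell by 3.47 (SE 0.18, adjusted p = 0.00032), from 2.55 ± 0.01 (SD, n = 2) to -0.92 ± 0.21 (SD, n = 3). Dntt, the terminal transferase that adds untemplated nucleotides, fell by 2.85 (SE 0.24, adjusted p = 0.0015), and Xrcc6, which encodes the end-joining protein Ku70, by 2.17 (SE 0.22, adjusted p = 0.0023). The recombinase genes Rag1 and Rag2 fell 2.52- and 2.61-fold. The mean log2 fold change of the list was -1.16 (camera adjusted p = 0.00098; adjusted p = 0.30 with an estimated correlation).

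Of 15 tested p53 pathway and apoptosis genes 7 were lower and 2 higher, with the same counts when adjusted over the list alone. The cell-cycle inhibitor Cdkn1a fell by 2.57 (SE 0.20, adjusted p = 0.0012), Phlda3 was 3.99-fold lower (SE 0.17 on the log2 scale, adjusted p = 0.0016), and Pmaip1, which encodes the pro-apoptotic protein Noxa, had a log2 fold change of -1.58 (SE 0.16, adjusted p = 0.0025). Bcl2l1, which encodes an anti-apoptotic protein, was also among the lower genes, and the pro-apoptotic Bid and Bcl2l11 were the higher ones, though other Bcl2l11 probes had log2 fold changes from -0.89 to -0.46 against 0.60. The mean log2 fold change was -0.71 (camera adjusted p = 0.00053; adjusted p = 0.30 with an estimated correlation).

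The cell-cycle list was lower by camera, with a wide spread between arrays. Of 26 tested members 5 were lower, 1, Myc, was higher and 20 did not pass (12 lower and 1 higher adjusted over the list alone). Cdk6, a kinase of the G1 phase, fell by 3.51 (SE 0.38, adjusted p = 0.0029), and the mitotic kinase gene Cdk1 and the mitotic cyclin gene Ccnb2 had log2 fold changes of -2.87 (SE 0.65, adjusted p = 0.030) and -2.49 (SE 0.66, adjusted p = 0.048). The mean change of the list against the control mean was -2.11 in deleted 4, -1.22 in deleted 5 and -0.63 in deleted 7, while the controls stood at 0.40 and -0.40. Camera gave an adjusted p of 0.00016 (adjusted p = 0.60 with an estimated correlation), and fry one of 0.280. Cdk1 and Ccnb2 did not pass without control 3 (adjusted p = 0.170 and 0.251), control 6 (0.0700 and 0.0789) or deleted 5 (0.0904 and 0.103), nor, with all arrays, without the variance trend (0.0636 and 0.0931) or with robust variances (0.0509 and 0.0998). Ccnb2 also did not pass with median scaling (0.0518), without the filter (0.0701), in the fit on probe means (0.0569) or over every probe (0.0535), with its own value unchanged in the last 3. Without deleted 4 the log2 fold changes of Cdk1 and Ccnb2 were -2.25 and -1.81, the mean of the Cdk1 probes gave -1.66, and Cdk6 stood at -2.84 without control 3 and -4.17 without control 6.

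The glycolysis and hypoxia list gave 2 lower and 0 higher of 16 tested members, also when adjusted over the list alone. Bnip3 fell by 2.20 (SE 0.40, adjusted p = 0.015) and the phosphofructokinase gene Pfkp had a log2 fold change of -1.67 (SE 0.39, adjusted p = 0.034), though other Pfkp probes gave log2 fold changes from -1.26 to -0.13. The mean log2 fold change was -0.87 (camera adjusted p = 0.0015; adjusted p = 0.60 with an estimated correlation). Control 6 and deleted 7 had nearly equal list means (-0.51 and -0.50 against the control mean), and the list call was lost without control 3 (adjusted p = 0.12). Bnip3 did not pass without control 3 (adjusted p = 0.0565) or deleted 5 (0.0624), nor Pfkp without control 3 (0.194), deleted 4 (0.0671), deleted 5 (0.0897) or, with all arrays, the variance trend (0.0706). With fry the list gave an adjusted p of 0.280, and the log2 fold change of Bnip3 was -1.57 without control 3 and -2.83 without control 6.

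In the IL-7 receptor and STAT5 list, 3 of 13 tested members were lower and 2 higher, with the same counts when adjusted over the list alone, and the list as a whole did not pass (mean log2 fold change -0.11, median 0.04, camera adjusted p = 0.90). Il7r, the receptor for the interleukin on which these cultures grow, fell by 3.86 (SE 0.53, adjusted p = 0.0059), from 4.49 ± 0.07 (SD, n = 2) to 0.63 ± 1.02 (SD, n = 3), and its other probes gave log2 fold changes of -3.63 and -2.62. Osm, a cytokine gene, fell by 1.98 (SE 0.25, adjusted p = 0.0044; second probe -2.75), whereas Socs3, a suppressor of cytokine signalling, rose by 2.32 (SE 0.19, adjusted p = 0.0014).

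**Figure D3:**
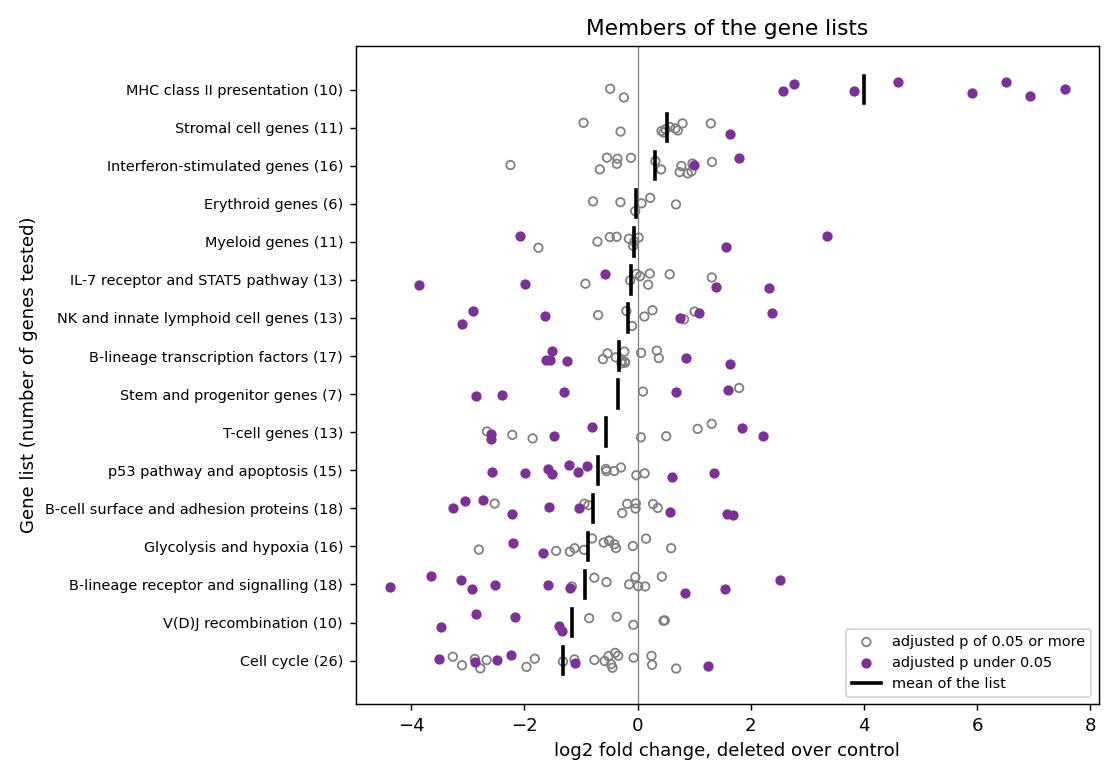
Log2 fold change of deleted over control (horizontal axis) for every tested member of the 16 gene lists (vertical axis, number tested in brackets), with filled points past an adjusted p of 0.05 and a black bar at each list's mean. The MHC class II list has the highest mean, 3.99, and the cell-cycle list the lowest, -1.32.

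Of the lists of other lineages none passed camera with the settings used here, though the T-cell list did with the filter at the 60th percentile (adjusted p = 0.00608, mean log2 fold change -1.57) and over every probe (0.0495). Over every probe, where genes with several probes count more than once, the stem and erythroid lists also passed (9.95e-07 and 0.0222). In the NK and innate lymphoid list 3 genes were higher and 3 lower of 13 tested (3 and 3 adjusted over the list alone; mean log2 fold change -0.17, median 0.12, camera adjusted p = 0.90). Klrb1c and Nkg7 had log2 fold changes of -3.11 (SE 0.31) and -2.91 (SE 0.64), and the chemokine gene Ccl5 rose by 2.38 (SE 0.24; second probe 3.14). The mean of the Klrb1c probes gave -1.95, and Nkg7 stood at -1.76 without control 3 and -4.06 without control 6. The lower genes also included Id2, an inhibitor of E proteins, which had a log2 fold change of -1.63. In the T-cell list 4 genes were lower and 2 higher of 13 (7 and 2 adjusted over the list alone; mean log2 fold change -0.55, camera adjusted p = 0.15). Dtx1 and the adaptor gene Lat each fell by 2.59 (SE 0.21 and 0.35), and Cd3g, low in both controls, was at least 3.26-fold higher. In the myeloid list 2 genes were higher and 1 lower of 11 (2 and 3 adjusted over the list alone; mean log2 fold change -0.07, camera adjusted p = 0.58). The transcription factor Cebpb rose by 3.34 (SE 0.32) and the adaptor Tyrobp by 1.56 (SE 0.22), while the integrin gene Itgam fell by 2.09 (SE 0.56, adjusted p = 0.049). Nkg7 did not pass without control 3, deleted 5 or deleted 7 (adjusted p = 0.0829, 0.0844 and 0.0575), nor Itgam without control 3, control 6, deleted 5 or deleted 7 (0.170, 0.162, 0.0605 and 0.0646). With all arrays neither passed without the variance trend (0.0536 and 0.0814), and Itgam did not with median (0.0533) or quantile scaling (0.0553), without the filter (0.0794), with probe means (0.0555) or over every probe (0.0533).

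In the stem and progenitor list 3 genes were lower and 2 higher of 7 tested (3 and 3 adjusted over the list alone; mean log2 fold change -0.34, median 0.10, camera adjusted p = 0.65). The receptor gene Kit fell by 2.86 (SE 0.33, adjusted p = 0.0036), Tal1 had a log2 fold change of -2.40 (SE 0.36, adjusted p = 0.0081), and Meis1 rose by 1.60 (SE 0.35, adjusted p = 0.026). Tal1 exceeded the 40th percentile in 1 of 3 deleted arrays and Meis1 in 1 of 2 controls. Tal1 did not pass without control 3 (adjusted p = 0.0676), nor Meis1 without control 3, control 6, deleted 4 or deleted 5 (0.139, 0.0598, 0.0609 and 0.0675) or as the mean of its probes (0.197), of which the second gave 0.77. Of 6 erythroid genes 0 passed in limma (0 adjusted over the list alone, 0 at an unadjusted p under 0.05, mean log2 fold change -0.03, median 0.01, camera adjusted p = 0.75), with Epor at a log2 fold change of -0.79 (SE 0.61, adjusted p = 0.41). In the stromal list 1 of 11 genes passed (1 adjusted over the list alone, mean log2 fold change 0.53, camera adjusted p = 0.14, and 0.0398 without deleted 5), Sparc rising by 1.63 (SE 0.21, adjusted p = 0.0053, second probe 2.38). The stromal list mean against the control mean was 0.86, 0.15 and 0.57 in deleted 4, 5 and 7, and 0.08 and -0.08 in controls 3 and 6. Whether stromal cells were carried over unequally was not tested. Of 16 interferon-stimulated genes 2 were higher (2 adjusted over the list alone; camera adjusted p = 0.58), Ifit3 by 1.80 (SE 0.39) and Mx2 by 1.00 (SE 0.20), and the list mean was 1.05 in deleted 7 against -0.21 and 0.06 in deleted 4 and 5. Neither gene passed without control 3 (adjusted p = 0.137 and 0.0744), control 6 (0.0780 and 0.0794) or deleted 5 (0.0898 and 0.0610). With all arrays Ifit3 did not pass without the variance trend (0.0578) or with array weights (0.0562), nor Mx2 without scaling (0.0720).

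Sex-linked genes split each group, so the samples of each group came from more than 1 embryo. Whether deleted 4 and deleted 5 came from separate embryos is not shown. Xist, expressed from the inactive X chromosome, stood at 4.67 in control 6 and 4.24 in deleted 7 and between -6.93 and -6.27 on the other arrays, and the Y-linked gene Eif2s3y stood at -7.51 and -7.03 on those same 2 arrays and between 2.01 and 3.13 on the others. Of 4 sex-linked genes 0 passed in limma (0 at an unadjusted p under 0.05; Xist log2 fold change -2.02, SE 4.24, adjusted p = 0.79). With the arrays high in Xist as a block, a fit chosen after the data were seen, 1483 genes changed, 699 of them higher, and Igll1, Bst1, Ccnb2, Itgam, Meis1 and Pfkp did not pass (adjusted p = 0.0509, 0.0563, 0.0819, 0.0841, 0.0579 and 0.0628). Their log2 fold changes were then -4.20, -2.87, -2.42, -2.01, 1.60 and -1.64, against -4.39, -3.06, -2.49, -2.09, 1.60 and -1.67 without the block, on 2 residual degrees of freedom. Among the arrays low in Xist alone, 1 control and 2 deleted, 1550 genes changed, 715 of them higher, but the spread there comes from the 2 deleted arrays alone and the lone control is assumed to vary like them. In that fit Rcan2, Itgam, Meis1, Ifit3 and Mx2 did not pass (adjusted p = 0.0578, 0.141, 0.0629, 0.0749 and 0.133), with log2 fold changes of -5.82, -2.11, 1.83, 1.58 and 0.80. Nor did the lists of receptor and signalling genes, transcription factors and surface proteins (camera adjusted p = 0.0597, 0.117 and 0.0621), whose mean log2 fold changes were -1.05, -0.32 and -0.80 against -0.92, -0.32 and -0.79 with all arrays. Some named genes that still passed there moved by over 1.5 times, to log2 fold changes of 7.96 for Ly86, -7.42 for Scin, -5.58 for Igll1, -4.72 for Vpreb2, -4.47 for Il7r, -4.33 for Cdk6, -3.94 for Bst1, -3.94 for Nkg7, -3.79 for Cdk1, -3.45 for Ccnb2, -3.07 for Bnip3 and -2.43 for Pfkp. The means of the cell-cycle and glycolysis lists were -2.01 and -1.57 there, against -1.32 and -0.87 with all arrays. The MHC class II list passed with the block (camera adjusted p = 9.81e-08), and the arrays high in Xist, 1 of each group, allow no test.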

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

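Scaling by the 75th percentile over named probes alone, a fit with the arrays high in Xist as a block, and a fit of the arrays low in Xist alone were chosen only after the data were seen, and the other alternatives were planned. No paired analysis was possible because the groups share no replicate numbers. Of the 54 named genes past the threshold, Ebf1 not counted, 47 were tested under all 19 alternatives other than the thresholds and 33 of them kept their call, while 40 were tested and kept under the 13 that keep all arrays. The other 7 were not tested under at least 1 alternative; of these Rpl3l, Ttll11, Slc9a2 and Cd3g kept their call where tested, and Nkg7, Tal1 and Meis1 lost it under some. None of the 54 changed direction where tested, and Epor, which did not pass, had a log2 fold change of 0.0076 in the arrays low in Xist. Genes changed were 2324 and ranged from 703 to 2009 with 1 array left out, where fewer samples, and a lone control assumed to vary like the other arrays, weaken the test. Higher genes then ranged from 388 to 974, lower genes from 315 to 1035 and genes changed at least 2-fold from 697 to 1603. With the Xist block 1483 genes changed, 699 of them higher, on 2 residual degrees of freedom, and in the arrays low in Xist, with 1, there were 1550, of which 715 were higher. Testing every probe gave 3587 changed probes, 1926 of them lower and 2664 changed at least 2-fold. An adjusted p of 0.01 gave 734 genes (351 higher, 383 lower, 708 at least 2-fold), one of 0.1 gave 3555 (1864 higher), and a test against a 1.5-fold change gave 670 (290 higher, 380 lower). Fewer genes were higher without scaling (669) and without the variance trend (761); the cause was not tested. The median log2 fold change of all genes was 0.10 as reported, 0.15 after median scaling, -0.04 without scaling and 0.17 without the filter, so small changes are relative to that shift. The mean of the 3 Ebf1 probes, which takes in AK036716, had a log2 fold change of -0.94 and passed. Signal over background limits dim genes, since no spot flags were used.

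With an estimated correlation no list passed. Adjusted p was 0.330 for B-lineage receptor and signalling, 0.376 for transcription factors, 0.303 for V(D)J recombination, MHC class II and p53, 0.521 for surface proteins, and 0.596 for cell cycle and glycolysis. With fry it was 0.0902 for receptor and signalling, transcription factors and surface proteins, and 0.280 for cell cycle and glycolysis, while V(D)J recombination, MHC class II and p53 passed. Without the variance trend the transcription factors gave 0.0590. The T-cell list passed with the 60th percentile filter (0.00608) and over every probe (0.0495), and over every probe so did the stem (9.95e-07) and erythroid (0.0222) lists, where genes with several probes count more than once. With the Xist block the transcription factors gave 0.0581. In the arrays low in Xist adjusted p was 0.0597 for receptor and signalling, 0.117 for transcription factors and 0.0621 for surface proteins. With 1 array left out, adjusted p ranged from 0.00467 to 0.153 for receptor and signalling, 0.0198 to 0.153 for transcription factors, 0.00680 to 0.153 for surface proteins, 6.31e-07 to 0.124 for glycolysis, 0.0398 to 0.290 for stromal genes, 0.384 to 0.971 for NK genes, 0.630 to 0.973 for the IL-7 list and 0.0869 to 0.973 for interferon genes. For lists that did not pass, the direction given by the set test turned, which is not the sign of the mean log2 fold change, and the cause was not tested. It turned for NK genes without control 3 (0.779), under quantile scaling (0.992), no scaling (0.942), probe means (0.965), every probe (0.814), no variance trend (0.984) and fry (0.280). It turned for myeloid genes under probe means (0.988) and fry (0.662), for stem genes under the 60th percentile filter (0.950), for the IL-7 list without scaling (0.937), with fry (0.831), with the Xist block (0.877) and without deleted 4 (0.701), and for interferon genes without deleted 7 (0.845) and in the arrays low in Xist (0.524). The mean itself turned for NK genes (0.10) without control 3, the IL-7 list (0.04) without deleted 4, and interferon genes without deleted 7 (-0.03) and in the arrays low in Xist (-0.17). The myeloid mean became positive without the filter (0.12), with the 60th percentile filter (0.02), under probe means (0.17), without control 3 (0.09) and without deleted 4 (0.02). The erythroid mean did so under median scaling (0.03), quantile scaling (0.0044), without control 6 (0.14), without deleted 4 (0.04) and in the arrays low in Xist (0.02).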

Other observations

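The tests of macrophage markers and of the difference between Ebf1 probes were chosen only after the result was seen, and the 3 marker lists used here were written after the fit of all genes was seen. A few members of the dendritic and later B-cell lists had been seen by then. In the later B-cell stage list more genes were higher than lower in deleted cells. Since the list was written after the fit was seen, its set test is no independent support. Of 14 tested members 9 were higher and 1, Zbtb20, was lower (9 and 1 adjusted over the list alone; camera adjusted p = 0.0073 over the 3 lists; adjusted p = 0.48 with an estimated correlation), and 3 of the list's genes are also in the fixed lists. Ms4a1, which encodes CD20, had a log2 fold change of 3.08 (SE 0.25, limma adjusted p = 0.0014), the IgE receptor gene Fcer2a 2.73 (SE 0.58, adjusted p = 0.025) and the chemokine receptor genes Ccr6 and Cxcr5 2.24 and 1.38. Cr2 and Ighm did not pass, at -0.05 (95% interval -0.84 to 0.73) and 0.23 (95% interval -0.33 to 0.79). Among genes chosen after their values were seen, the costimulatory gene Cd86, Cd83, the protease gene Ctsh and Apoe had log2 fold changes of 5.23, 4.66, 5.85 and 5.21, with Cd86 above the 40th percentile in 1 of 2 controls.

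MHC class II genes past the threshold had a median log2 fold change of 5.26. Macrophages mixed into the deleted cultures would bring their other abundant transcripts, but the macrophage markers had a median of 0.2104 (quartiles -0.35 and 0.49) over all named members, with 1 of 9 tested members higher (Tyrobp, 1.56) and 2 lower (camera adjusted p = 0.37), and Lyz2 stood at -1.75 (adjusted p = 0.055). The dendritic cell markers had a median of 0.2357 (quartiles 0.04 and 0.34), with Ccr7 and Ccr9 higher and Flt3 lower of 11 tested (camera adjusted p = 0.40). Neither marker set rose as a whole like the MHC class II genes. The medians take in dim markers, as 9 of 15 named macrophage and 11 of 16 named dendritic markers were tested. Both lists were written after the fit was seen, so they are no independent evidence against those cells as the whole source. Other genes that such cells express did rise, with log2 fold changes of 7.58 for Wfdc17, 7.07 for Ly86 and 3.34 for Cebpb beside Apoe, Cd86 and Ctsh above, so cells that carry these genes without the listed markers stay open; 7 and 2 genes of the lists are also in the fixed lists. A shift of the culture towards later B-cell stages stays open as a hypothesis, with a median of 0.9179 (quartiles 0.05 and 2.03), as does an effect of Ebf1 loss on these genes, which was not tested apart from the title number.

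The Ebf1 probes for AK036716 and NM_007897 differed in their log2 fold changes by -2.773 within arrays (SE 0.50, 95% interval -3.98 to -1.57, limma adjusted p = 0.015). As the only remaining source of Ebf1 transcript, undeleted cells left in the cultures would limit the fall of every Ebf1 probe alike. The size of this difference argues against them as the whole cause. The pair was picked after its values were seen, so its p-value is no independent support, and the dim AK042875 probe was not part of the test. A transcript that keeps the part read by the brighter probe may explain the difference, but it was not tested because the probes' positions were not used here.

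Cdkn2a, a cell-cycle inhibitor gene, was chosen after its values were seen, and which of its transcripts the spots read was not determined. Its brightest spot had a log2 fold change of -5.47 (SE 0.44, limma adjusted p = 0.0013), -4.77 without control 3 and -6.17 without control 6. That spot exceeded the 40th percentile on all 3 deleted arrays. Of the 10 Cdkn2a spots 2 did so on none of them, and these were at least 63.7-fold and 67.0-fold lower. Those limits were 40.3-fold and 43.9-fold without control 3 and 100.8-fold and 102.2-fold without control 6. The neighbouring inhibitor gene Cdkn2b had -3.75 (SE 0.30, adjusted p = 0.0013). The Cdkn2b spot still exceeded the 40th percentile on all 3 deleted arrays. Its intensities were 50.1, 59.5 and 47.4 in deleted 4, 5 and 7, against 863 and 680 in controls 3 and 6. That signal cannot decide whether the genomic region was lost from every pro-B cell of the deleted cultures. How background was handled is not given, and the cultures were grown on stromal cells. Loss from some cells was not tested. The other neighbour of Cdkn2a, Mtap, had a log2 fold change of 0.2459 (95% interval -0.22 to 0.71). Such a loss would have to end between Cdkn2a and Mtap, and without DNA data it cannot be told apart from lower transcription.

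Of 100 tested neighbours of Ebf1 24% changed (exact 95% interval 16.02 to 33.57), 7 higher and 17 lower, against 17.3% of all genes (one-sided Fisher's exact p = 0.0548). The largest shift of an autosome's median log2 fold change relative to all genes was -0.09413, on chromosome 18. Of the 10 splits of the 5 arrays into 2 and 3, 1 gave as many changed genes, the real one with 2324. The highest other gave 3. Every other split puts control and deleted arrays in 1 group, which widens the spread there and lowers the count. The contrast is thus no measure of chance, and 10 splits are too few for a share under 0.05.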
